A study of Homo sapiens with 16 samples.

How the data were processed

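RNA sequencing was done on T cells grown from the blood mononuclear cells of 4 donors and collected on day 7. The cells had been stimulated through CD3 and CD28, either on commercial beads or on a graphene oxide antigen-presenting platform (GO-APP), each with and without added IL-2. Each donor gave 1 library to each of the 4 groups, 16 libraries in all. Per the labels' protocols, the IL-2 dose was 30 U/ml on beads; no dose is given for GO-APP in the sources used here. The protocol text describes only beads with IL-2 and GO-APP without IL-2; the other 2 groups come from the treatment and agent labels of the samples. RNA was extracted with the miRNeasy Micro kit, and stranded total RNA libraries were read as 50 bp single ends on a HiSeq3000, per the labels' protocols.

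The deposited file gives 1 signal per gene symbol and library, for 31953 symbols. Per the submitters' processing notes, STAR 2.5.3a and DESeq2 were used with the hg38 build. The counting program, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Each library's deposited signal values were whole multiples of 1 step, for 100% of values within a tolerance of 1e-06, so they are read counts divided by 1 size factor per library. Size factors recomputed from the recovered reads by DESeq2's median of ratios differed from these steps by at most 4.9e-15 of their value. They are called normalized read counts here. No column belonged to no sample.

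The 16 libraries held 16671041 to 20452002 recovered reads (mean 18740000). At this depth, a gene with no read in a library could hold up to 3 counts per library; that floor covers counting error only, and was used for each fold against a group at 0. Symbols were matched to GENCODE release 29 for identifiers, gene types and hg38 coordinates: 31139 symbols of the file and 15346 of the symbols tested had a match, and 12627 of those tested were protein coding. XIST and Y-linked genes (56 symbols) were left out of all tests, and HLA genes and receptor variable segments were never tabulated per sample.

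Genes with a value of at least 10 in at least 4 libraries were tested (15642 genes). The test was limma-trend with robust moderation on log2(value + 1), with 1 fit for all 16 libraries and 1 mean per group, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The design had named edgeR for raw counts and limma for normalized values; the values were normalized, so limma was used. A log2 fold change on this scale understates the fold of genes with low values. A ± after a mean is the SD over 4 libraries; a ± after a log2 fold change is limma's SE. The comparisons were GO-APP without IL-2 against beads with IL-2, GO-APP against beads at each IL-2 setting, IL-2 against none on each platform, and the platform by IL-2 interaction.

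The gene lists of the report were fixed before the data were examined, as were the tests of its comparisons, the rule for named genes and the alternatives other than the fit of the groups compared with the donor block. Tests chosen later are named where they are given. The 42 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison; 2 lists were too small. Named genes were those called, protein coding, with a mean of at least 50 in the higher group and a change in 1 direction in all 4 donors, ranked by fold change (up to 10 per direction, up to 12 in the comparison with IL-2 on beads alone). Where fewer than 5 passed in a direction, the genes with the smallest p filled up to 5. To these came 2 to 4 members with the smallest p of each list described and 16 key T cell genes. Some genes that this rule named are not reported here. Any gene outside this rule is said to be chosen after its values were seen.

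Libraries that share a replicate number come from the same donor, per the labels. Deviations from the group means correlated at a median of 0.338 over 24 same-donor pairs (0.168 to 0.839), against a median of -0.125 over 72 pairs of different donors (-0.6 to 0.23). A fit with the replicate as a block was therefore an alternative whose value stands beside a result where it changed the call. Other alternatives were TMM scaling (edgeR), pseudocounts of 0.1 and 10, no filter and a minimum of 50, DESeq2's Wald test and edgeR's quasi-likelihood test on recovered reads, a fit of only the groups compared, each replicate left out, and, for lists, an estimated correlation and fry. edgeR called 6672, 6647 and 7934 genes in the 3 platform comparisons (GO-APP without IL-2 against beads with IL-2, both without, both with) and 0 genes in each of the other 3.

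The limma test of each of the 5 comparisons of 2 groups was first run on simulated counts with 200 genes changed by known folds; the interaction was not simulated, and a shifted list was simulated for IL-2 on GO-APP alone. In the simulated comparison of GO-APP without IL-2 with beads with IL-2 (14814 genes), it recovered 1.59% of changes of 1.5-fold, 19.4% of 2-fold and 65.6% of 4-fold. In the simulated comparison of IL-2 with none on GO-APP (14832 genes), 1.61%, 15.9% and 64.1% were recovered. With the donor block, more was recovered (4.84%, 23.8% and 79.7%). Of its calls, 8.97% were false there, 9.09%, 10.1% and 4.05% in the platform comparisons, and 2.41% for IL-2 on beads. Each of these shares rests on a single run with 74 to 88 calls. The 200 changed genes are far fewer than differed between the platforms, so the shares are rough. Calls that need the block are still taken as less certain, by choice. The shares are too rough to show that the blocked fit makes too many false calls. The fit without the block leaves out the pairing of the donors. For IL-2 on beads (14837 genes), 1.61%, 17.2% and 58.5% were recovered, and 3.23%, 37.5% and 84.6% with the block. Computations used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.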

Results

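T cells from 4 donors were profiled by total RNA sequencing on day 7 after stimulation through CD3 and CD28. The stimulus was carried by commercial beads or by GO-APP, a graphene oxide platform carrying antibodies to the same 2 molecules, and each platform was used with and without added IL-2, the growth factor of T cells. There were 4 libraries in each of the 4 groups. Read totals averaged 18327000 ± 1534800 for beads without IL-2, 19024000 ± 918130 for beads with IL-2, 18101000 ± 616710 for GO-APP without IL-2 and 19509000 ± 908870 for GO-APP with IL-2. The T cell receptor gene CD3E was expressed in all groups, at means of 9984, 11210, 12360 and 13610 normalized read counts in that order. The 10 most abundant genes took 5.14%, 5.28%, 6.07% and 6.23% of the reads, and 21835, 21820, 20775 and 21156 genes were detected.

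The platform was the main difference among the libraries. It went with 58.1% ± 3.86 (jackknife SE over 4 donors) of the variance of the log2 values, the donor with 20.5% ± 2.31, IL-2 with 2.18% ± 0.893, and the platform by IL-2 interaction with 1.85% ± 0.679. The residual was 17.5% ± 1.73. All of these shares depended on the data used. Platform went with 46.1% without the filter on low values and 63.9% without replicate 2, and donor with 17.2% without replicate 2. The residual was 26.5% without the filter. IL-2 went with 3.37% without replicate 5, and the interaction with 2.87% without replicate 4 and 2.99% without the filter.

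**Figure D1:**
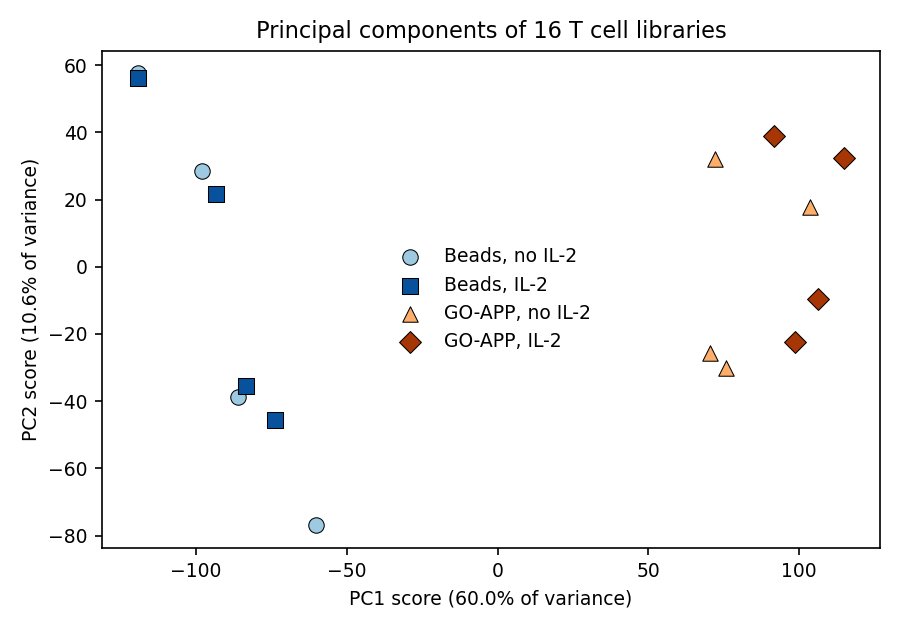
Each point is 1 library, placed by its scores on the first (PC1, 59.99% of variance) and second (PC2, 10.6%) principal components of the log2 values, with colour and shape for the group (n = 4 each). All 8 GO-APP libraries have PC1 scores of 70.4 or more and all 8 bead libraries scores of -60.2 or less.

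The labels' protocol sets GO-APP without IL-2 against beads with IL-2, which asks how cells expanded on GO-APP with no added cytokine differ from the usual bead culture. Genes of the metallothionein cluster, hypoxia-response genes and amino acid stress genes were higher on GO-APP, and type I interferon response genes were lower. With an estimated correlation between genes, 0 of 42 lists passed. In this comparison 6761 of 15642 genes changed (43.2%): 3333 rose and 3428 fell, 2217 and 2506 of them by at least 2-fold, and 6326 moved in 1 direction in all 4 donors. The largest rise was in MT1H, a metal-binding metallothionein (chromosome 16, 56669814 to 56671129, hg38), at 669.8 ± 421 against 2.23 ± 2.12 normalized read counts, a log2 fold change of 7.62 ± 0.63 (limma adjusted p = 5.88e-07, higher in 4 of 4 donors). On the lower side CCR2, the receptor for monocyte-attracting chemokines, was at 11.6 ± 18.6 against 948.1 ± 653, a log2 fold change of -6.91 ± 0.98 (limma adjusted p = 5.58e-05, lower in all 4 donors). The metallothionein genes are near-identical copies, so the split of reads among them is uncertain.

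Among the other genes reported by rule, those that rose had log2 fold changes from 6.20 (HES4, a Notch target) to 7.61 (MT1G). They were EEF1A2, a translation elongation factor, at 7.32, MT3 at 7.14, the vasodilator peptide gene ADM at 6.63, TMEM92 at 6.42, the collagen-modifying P3H3 at 6.31, the secreted hormone gene STC2 at 6.30 and the growth factor PDGFA at 6.23. MT1M had no read on beads with IL-2 and a mean of 116.7 on GO-APP, at least 43.2-fold higher against the floor of 3 counts per library. Those that fell were CLIC3 at -6.69, MEOX1 at -6.38, VSIG1 at -6.26, TMEM229B at -5.83, GPA33 at -5.69, RAP1GAP2 at -5.67, B3GALT2 at -5.66, the prostaglandin receptor PTGDR2 at -5.57 and the complement receptor C3AR1 at -5.36. KRT1 had no read on GO-APP against 55.7 ± 52.1 on beads, at least 16.9-fold lower. Limma's adjusted p for these genes ranged from 2.53e-07 to 0.000283.

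Metabolic and stress genes rose as groups on GO-APP. Among 32 hypoxia-response genes, 28 rose and 0 fell (29 rose adjusted over the list alone), with a median log2 fold change of 2.85 (upper quartile 3.98). The angiogenic factor VEGFA was at 2071 ± 707 against 32.2 ± 19.8 (6.13 ± 0.52), the prolyl hydroxylase P4HA1 at 3.79 ± 0.30 and the mTOR inhibitor DDIT4 at 4.04 ± 0.34 on the log2 scale. Camera gave adjusted p = 1.21e-12 for this list, and adjusted p = 0.364 with an estimated correlation. Of 22 glycolysis genes, some of which the hypoxia list also holds, 16 rose and 0 fell (17 rose adjusted over the list alone), median 1.31 (camera adjusted p = 8.37e-06; adjusted p = 0.538 with an estimated correlation). The glucose transporter SLC2A3 was at 3.78 ± 0.41, the enolase ENO2 at 2.74 ± 0.28 and the aldolase ALDOC at 2.99 ± 0.36. The list of amino acid and ATF4 response genes, which are induced when amino acids run short, had 29 of 34 members higher and 1 lower (30 and 1 adjusted over the list alone), median 1.89 (camera adjusted p = 1.09e-10; adjusted p = 0.364 with an estimated correlation). Its examples were the lipoprotein receptor VLDLR at 1328 ± 219 against 31.4 ± 3.58 (5.35 ± 0.25) and the transcription factor ATF3 at 3.86 ± 0.46. For the metallothioneins and metal-response genes, 8 of 11 rose and 0 fell (9 rose adjusted over the list alone), median 4.31 with MT1M above it, and MT1X was at 5.50 ± 0.58 (camera adjusted p = 1.84e-05; adjusted p = 0.364 with an estimated correlation).

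Lipid synthesis and protein folding genes were also higher on GO-APP, and p53 targets shifted upwards as a list. Of 28 genes of cholesterol and fatty acid synthesis, 22 rose and 2 fell (23 and 3 adjusted over the list alone), median 1.17 (camera adjusted p = 1.82e-06; adjusted p = 0.364 with an estimated correlation). The desaturase SCD was at 10760 ± 2686 against 695.9 ± 375 (4.06 ± 0.39), FADS1 at 4.06 ± 0.50 and the regulator SREBF2 at 1.48 ± 0.16. The unfolded protein response list had 14 of 23 members higher and 0 lower (15 and 0 adjusted over the list alone), median 0.76 (camera adjusted p = 0.000218; adjusted p = 0.364 with an estimated correlation). HERPUD1 was at 2.33 ± 0.21 and the chaperone HSP90B1 at 1.41 ± 0.27. Among p53 targets and cell death genes, 13 of 28 rose and 4 fell (16 and 5 adjusted over the list alone), median 0.67 (camera adjusted p = 0.0138; adjusted p = 0.364 with an estimated correlation). The death receptor TNFRSF10B was at 1.39 ± 0.17 and GADD45A at 1.99 ± 0.31. Both BBC3, which promotes cell death, and BCL2, which opposes it, rose, by log2 1.51 and 1.59. The p53 list did not pass between the platforms when both were without IL-2. With IL-2 on beads, which is part of the present comparison, that list shifted downwards.

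Genes that T cells switch on when stimulated were higher on GO-APP. For the immediate early genes of the T cell receptor, 16 of 27 rose and 1 fell (the same counts adjusted over the list alone), median 1.37 (camera adjusted p = 0.000158; adjusted p = 0.364 with an estimated correlation). FOSL2 was at 2.04 ± 0.22, the phosphatase DUSP2 at 2.19 ± 0.31 and IER3 at 3.87 ± 0.60. Of 23 T cell activation genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), median 1.32. The costimulatory receptors TNFRSF4 (OX40) and TNFRSF18 (GITR) were at log2 3.52 ± 0.49 and 3.59 ± 0.51, and the adhesion molecule ICAM1 at 2.16 ± 0.28 (camera adjusted p = 0.0011; adjusted p = 0.429 with an estimated correlation). The NF-kB list had 12 of 23 members higher and 2 lower (14 and 2 adjusted over the list alone), median 0.95 (camera adjusted p = 0.0011; adjusted p = 0.364 with an estimated correlation). NFKB2 was at 1.35 and its inhibitor TNFAIP3 at 1.44, while lymphotoxin beta (LTB) fell by 3.32 on the log2 scale. Among IL-2 and STAT5 targets, 13 of 29 rose and 3 fell (14 and 3 adjusted over the list alone), median 0.67 (camera adjusted p = 0.012; adjusted p = 0.76 with an estimated correlation). NFIL3 was at 4.27 ± 0.40 and PIM1 at 1.25 ± 0.22.

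Single effector and checkpoint genes stood out. The protease gene GZMB was at 31220 ± 10280 on GO-APP against 3306 ± 2819 on beads with IL-2 (log2 3.83 ± 0.91, limma adjusted p = 0.00309), IFNG at 1484 ± 721 against 199.3 ± 55.9 (2.81 ± 0.49, 0.000293) and the inhibitory receptor LAG3 at 10690 ± 3423 against 869.1 ± 294 (3.63 ± 0.29, 4.72e-07), each higher in 4 of 4 donors. PDCD1, which encodes PD-1, was at log2 1.75, the IL-2 receptor alpha chain IL2RA at 1.99 and CD4 at 0.94, all called. PRF1 (0.41 ± 0.25), IL2 (1.38 ± 0.73), IL2RB (0.26 ± 0.33), CISH (0.36 ± 0.58), CD8A (-0.41 ± 0.62) and MKI67 (0.44 ± 0.39) did not pass. PDCD1 (1.17) and CD4 (0.79) lost their calls without replicate 5, and CD4 (0.69) without replicate 2. The 26 cytotoxic effector genes went both ways, 11 up and 7 down (12 and 7 adjusted over the list alone) (camera adjusted p = 0.321). CST7 was at 2.76, SRGN at 1.71 and CCL3 at 4.32 against LAMP1 at -0.95. Exhaustion and inhibitory receptor genes gave 7 up and 3 down of 24 (camera adjusted p = 0.254). CTLA4 was at 1.55, NR4A1 at 3.55 and HAVCR2 at 2.13.

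**Figure D2:**
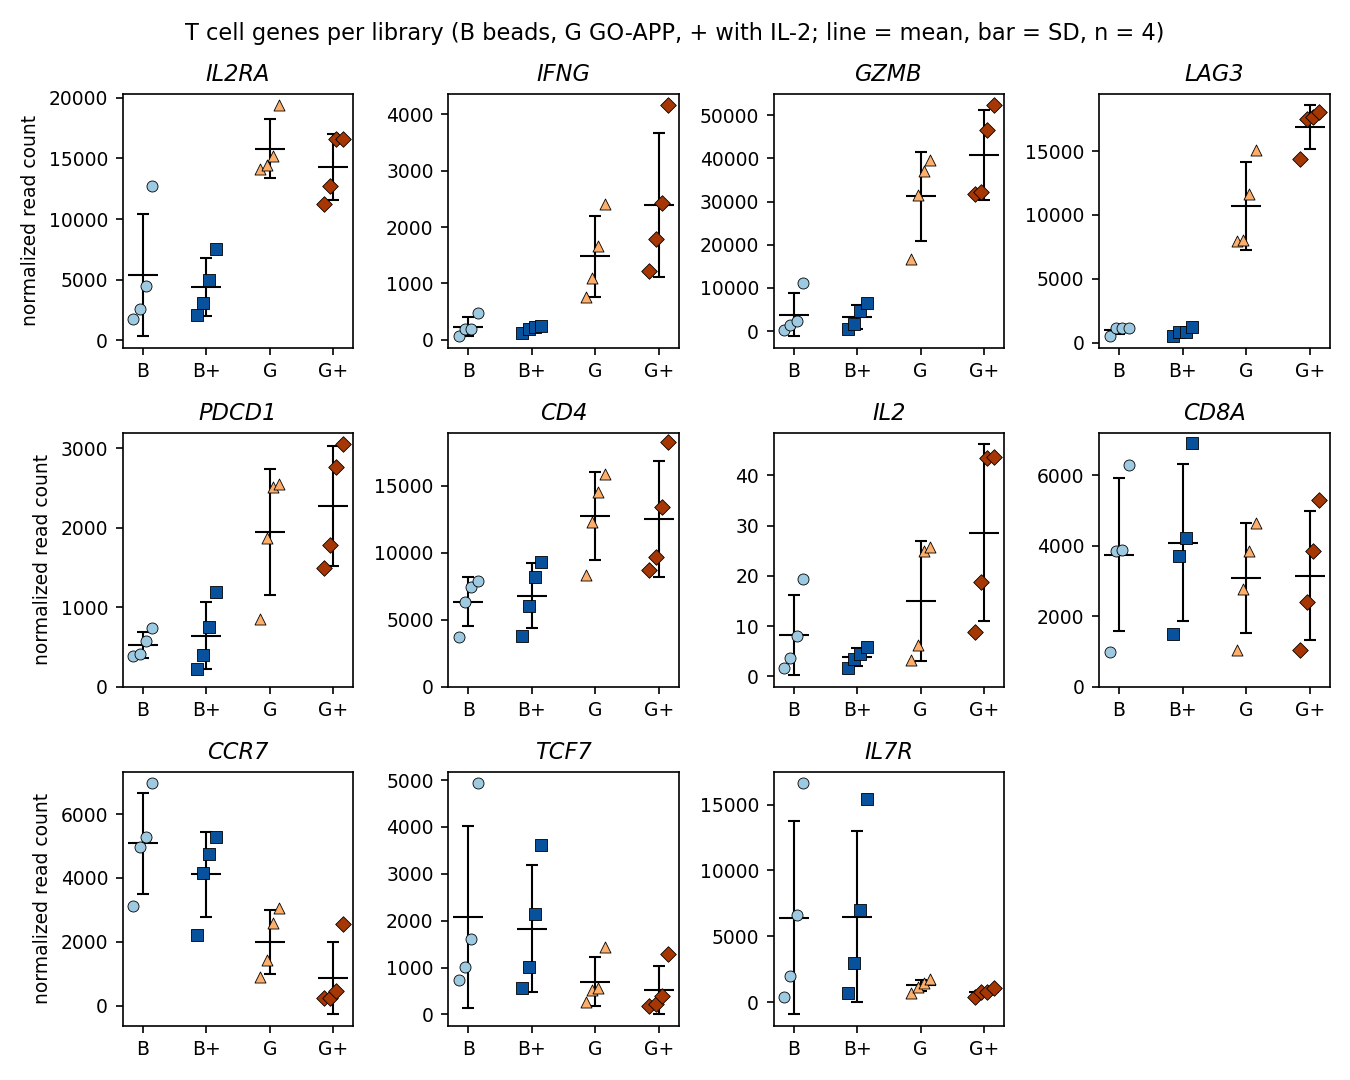
Normalized read counts of 11 T cell genes, 1 point per library (n = 4 per group), with the group mean as a line and the SD as a bar. LAG3, GZMB, IFNG, IL2RA, PDCD1 and CD4 have higher means on GO-APP at both IL-2 settings, and CCR7, TCF7, IL7R and CD8A lower means; CD8A was not called at either setting without the donor block.

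Type I interferon response genes were lower on GO-APP, and the lists of interferon gamma response and adhesion genes shifted downwards. Of 43 type I interferon response genes, 24 fell and 1 rose (26 and 2 adjusted over the list alone), median -1.64 (camera adjusted p = 0.000185; adjusted p = 0.76 with an estimated correlation). The RNA sensor DDX58 was at 97.8 ± 9.07 against 1042 ± 378 (-3.32 ± 0.39) and SAMD9L at -3.67 ± 0.55. Interferon gamma response and antigen presentation genes fell in 10 of 27 cases and rose in 2 (12 and 2 adjusted over the list alone), median -0.41, with the GTPases GBP1 at -2.81 ± 0.28 and GBP4 at -2.26 ± 0.34. Camera gave adjusted p = 0.039, adjusted p = 0.054 with the donor block, which ends this call, and adjusted p = 0.76 with an estimated correlation. Among integrins, adhesion and cytoskeleton genes, 12 of 29 fell and 2 rose (12 and 2 adjusted over the list alone), median -0.53 (camera adjusted p = 0.0138; adjusted p = 0.364 with an estimated correlation). The integrin chains ITGA4 and ITGB7 were at -2.08 ± 0.22 and -1.80 ± 0.35 and the motor protein MYO1F at -2.63 ± 0.26. Chemokines and their receptors went both ways, 7 up and 10 down of 27 (camera adjusted p = 0.358). CCR4 was at -1.90 and CXCR3 at -1.73.

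Naive and central memory genes had 8 of 28 members lower and 2 higher (8 and 2 adjusted over the list alone), median -0.80. The water channel AQP3 was at -4.04 ± 0.56 and the quiescence factors KLF2 at -3.51 ± 0.59 and KLF3 at -2.27 ± 0.41. The list did not pass (camera adjusted p = 0.121) but did with the donor block (adjusted p = 0.0413; adjusted p = 0.488 with an estimated correlation in that fit). CCR7 (-1.13, adjusted p = 0.142), TCF7 (-1.32, 0.146) and IL7R (-1.66, 0.177) did not pass; with the donor block, limma gave adjusted p = 0.0459, 0.00228 and 0.0268. In the blocked fits that left out 1 replicate, TCF7 passed in all 4, CCR7 without replicate 4 alone (-1.36) and IL7R without replicate 2 alone (-2.25), and these 2 passed there without the block as well, as did TCF7 without replicate 4 (-1.32).

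The lists of mitosis and G2/M genes and of ribosomal protein genes shifted upwards on GO-APP. Of 40 mitosis genes, 23 rose and 0 fell (25 rose adjusted over the list alone), median 0.94 (camera adjusted p = 6.24e-05; adjusted p = 0.76 with an estimated correlation). The kinase NEK2 was at 1.78 ± 0.34 and the kinesin KIF2C at 1.81 ± 0.37. The ribosomal protein list had 23 of 48 members higher and 0 lower (23 and 0 adjusted over the list alone), median 0.59 (camera adjusted p = 1.84e-05; adjusted p = 0.76 with an estimated correlation). RPL4 was at 0.74 ± 0.21 and RPS6 at 0.78 ± 0.22. For nuclear genes of oxidative phosphorylation, 10 of 44 rose and 0 fell (2 rose adjusted over the list alone), a small shift of the list with a median of 0.34 (camera adjusted p = 0.0124; adjusted p = 0.797 with an estimated correlation). NDUFV2 was at 4.04 ± 0.33 and SDHA at 0.79 ± 0.21. DNA replication and G1/S genes gave 1 up and 3 down of 40 (camera adjusted p = 0.669).

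Marker genes of other cells were measured beside these groups. Summed dendritic cell markers were at 5218 ± 4160 on GO-APP without IL-2 and 887.6 ± 395 on beads with IL-2, with 3 of 7 tested markers higher and 0 lower (3 and 0 adjusted over the list alone): ZBTB46 at log2 3.67, CCL22 at 2.72 and BATF3 at 3.27. Activated T cells can express the last of these too, and CCL22 is also in the lists of NF-kB targets and of chemokines. Over the 16 dendritic cell markers in the file, the median marker was at 3.06 on GO-APP and 3.90 on beads. The higher sum of the dendritic list thus rests on part of its markers. That list passed only with the donor block (camera adjusted p = 0.0675 and, blocked, 0.0249; adjusted p = 0.442 with an estimated correlation in the blocked fit). So did the MHC class II genes, with 4 of 13 lower and 0 higher (4 and 0 adjusted over the list alone), among them the regulator CIITA at -1.20 and the protease CTSS at -0.79 (0.106 and, blocked, 0.0263; adjusted p = 0.693 with an estimated correlation in the blocked fit). Natural killer cell markers summed to 39890 ± 14480 and 17410 ± 7653 (4 up and 1 down of 17, camera adjusted p = 0.547), B and plasma cell markers to 5030 ± 2598 and 3329 ± 1404 (2 up and 1 down of 20, 0.547), and monocyte and macrophage markers to 1431 ± 638 and 1381 ± 368 (0 up and 3 down of 16, 0.924; their median log2 fold change was 0.19, against a downward direction in the test). The median natural killer cell marker was at 88.6 on GO-APP and 84.35 on beads, so the higher sum rests on part of those markers. They include IL2RB, a key T cell gene here, and GNLY, also a cytotoxic effector gene here. The lists of platelet and erythroid markers (46.8 and 27.6) and of granulocyte and mast cell markers (267 and 81.0) were too small to test.

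The remaining lists did not pass in this comparison. Camera's adjusted p was 0.057 for heat shock genes (4 of 14 up, 0 down) and 0.057 for nuclear RNAs used as a sign of RNA quality (4 of 7 up, 0 down). Cytokine genes of activated T cells gave 0.137 (11 up, 4 down), NRF2 targets 0.147 (6 and 1), mitochondrially encoded genes 0.202 (0 and 6), MYC and ribosome biogenesis genes 0.228 (5 and 8), Treg genes 0.271 (7 and 3), histone genes 0.388 (0 and 2) and Th17 genes 0.445 (5 and 1). CD4 lineage genes gave 0.66 (2 and 2), CD8 lineage genes 0.66 (2 and 2), gamma delta T cell genes 0.796 (1 and 0), Th1 genes 0.796 (9 and 5), iron handling genes 0.796 (0 and 1) and Th2 genes 0.803 (5 and 5). Camera passed 17 of the 42 lists at its preset correlation and 0 with an estimated one. Platform and IL-2 both differ between these groups, so this comparison does not separate them.

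At a matched setting without IL-2, platform is the only factor named in the labels that differs between GO-APP and bead cultures. The protocol text does not describe beads without IL-2, so other differences in culture cannot be excluded. The hypoxia gene VEGFA was again higher on GO-APP and CCR2 lower. VEGFA was at 2071 ± 707 on GO-APP against 36.3 ± 40.3 on beads (log2 6.24 ± 0.52, limma adjusted p = 6.42e-07), and CCR2 at 11.6 ± 18.6 against 645.9 ± 381 (-6.72 ± 0.98, 7.52e-05). In all, 6692 genes changed (42.8%), 3321 up and 3371 down, 2222 and 2451 by at least 2-fold, and 6211 in 1 direction in all 4 donors. MT1H led the rises at 8.52 ± 0.63, followed by MT1G at 7.43, EEF1A2 at 7.19, MT3 at 7.11, ADM at 6.90, HES4 at 6.26, the arginine synthesis enzyme ASS1 at 6.26 and CDC42EP1 at 6.17. MT1M was at least 41.5-fold higher than the floor on beads. Other falls were MEOX1 at -6.26, CLIC3 at -6.03, VSIG1 at -5.92, TMEM229B at -5.80, RAP1GAP2 at -5.71, B3GALT2 at -5.67, GPA33 at -5.39 and C3AR1 at -5.25.

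Gene groups in the cultures without IL-2 moved as follows. Hypoxia genes rose in 28 of 32 cases with 0 lower (28 and 0 adjusted over the list alone), median 2.81 (camera adjusted p = 4.92e-13; adjusted p = 0.428 with an estimated correlation). ATF4 response genes gave 28 up and 1 down of 34 (29 and 1 adjusted over the list alone), median 1.78 (1.41e-10; adjusted p = 0.428 with an estimated correlation). Cholesterol and fatty acid synthesis genes gave 20 up and 2 down of 28 (22 and 3 adjusted over the list alone), median 1.25 (7.52e-07; adjusted p = 0.428 with an estimated correlation). Glycolysis gave 16 up and 0 down of 22 (17 and 0 adjusted over the list alone), median 1.33 (4.14e-06; adjusted p = 0.561 with an estimated correlation), and metallothioneins 9 up and 0 down of 11 (9 and 0 adjusted over the list alone), median 4.29 (3.01e-05; adjusted p = 0.428 with an estimated correlation). Type I interferon response genes fell in 27 of 43 cases and rose in 2 (29 and 2 adjusted over the list alone), median -2.04 (6.53e-06; adjusted p = 0.7 with an estimated correlation). Immediate early genes gave 19 up and 0 down of 27 (21 and 1 adjusted over the list alone), median 1.65 (1.94e-05; adjusted p = 0.428 with an estimated correlation).

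The weaker groups in this comparison were mitosis (24 up, 0 down of 40, median 0.92, camera adjusted p = 5.47e-05; adjusted p = 0.72 with an estimated correlation), ribosomal proteins (33 up, 0 down of 48, 5.94e-07; adjusted p = 0.7 with an estimated correlation) and the unfolded protein response (15 up, 0 down of 23, median 0.79, 0.000339; adjusted p = 0.428 with an estimated correlation). Activation genes gave 12 up and 1 down of 23 (0.0029; adjusted p = 0.524 with an estimated correlation), NF-kB targets 11 and 2 of 23 (0.00519; adjusted p = 0.428 with an estimated correlation), and IL-2 and STAT5 targets 12 and 2 of 29 (0.0101; adjusted p = 0.7 with an estimated correlation). Oxidative phosphorylation gave 10 up and 0 down of 44 (0.00519; adjusted p = 0.75 with an estimated correlation), interferon gamma response genes 2 up and 11 down of 27 (0.0299; adjusted p = 0.7 with an estimated correlation), and integrins and adhesion genes 2 up and 12 down of 29 (0.0323; adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone, the counts up and down were 26 and 0 for mitosis, 38 and 0 for ribosomal proteins, 15 and 0 for the unfolded protein response, 13 and 1 for activation, 12 and 2 for NF-kB, 12 and 2 for STAT5, 8 and 0 for oxidative phosphorylation, 2 and 11 for interferon gamma, and 2 and 12 for adhesion.

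With the donor block alone, 3 further lists passed: naive and central memory genes (2 up, 9 down of 28; adjusted p = 0.0862 and, blocked, 0.0236), dendritic cell markers (3 up, 0 down of 7; 0.0862 and 0.0298) and MHC class II genes (0 up, 3 down of 13; 0.109 and 0.0298). In the blocked fit they had adjusted p = 0.501, 0.459 and 0.624 with an estimated correlation. The list of p53 targets and cell death genes did not pass here, with or without the block. LAG3 (3.46 ± 0.29), GZMB (4.07 ± 0.91), IFNG (2.81 ± 0.49), IL2RA (1.97 ± 0.47), PDCD1 (1.82 ± 0.45), CD4 (1.02 ± 0.32) and PRF1 (0.69 ± 0.25) rose. CCR7 (-1.46, adjusted p = 0.0626) and TCF7 (-1.43, 0.117) passed only with the donor block (0.014 and 0.00133); the blocked call of CCR7 was lost without replicates 3 and 5, and without the block it passed without replicate 4 (-1.68). IL7R (-1.31), IL2 (0.81), IL2RB (0.41), CISH (0.56), CD8A (-0.21) and MKI67 (0.38) did not pass. The call of PRF1 was lost without replicate 2 (0.65), 3 (0.71) or 4 (0.51) and that of CD4 without replicate 2 (0.79) or 5 (0.92), while IL7R passed without replicate 2 (-2.08). Dendritic cell markers summed to 5218 ± 4160 on GO-APP and 1093 ± 507 on beads, and natural killer cell markers to 39890 ± 14480 and 13320 ± 3124. The median marker was at 3.06 and 2.53 for dendritic cells and at 88.6 and 76.8 for natural killer cells.

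Ribosomal RNA of the mitochondrial genome was higher on GO-APP, while 6 of its 13 messenger RNAs were lower and 0 higher without IL-2. The large ribosomal RNA gene MT-RNR2 was at 278100 ± 72770 on GO-APP against 72790 ± 9917 on beads without IL-2 (log2 1.91 ± 0.21, limma adjusted p = 7.33e-06, higher in 4 of 4 donors), and MT-RNR1 at 1.16 ± 0.33 (0.01). Among the messenger RNAs, MT-ATP8 fell by 2.04 on the log2 scale, MT-CO3 by 1.78, MT-ND6 by 1.68 and MT-ATP6 by 1.60, while MT-CO1 (0.18 ± 0.21, adjusted p = 0.514), MT-CO2 (0.15 ± 0.25), MT-ND4 (0.47), MT-ND4L (0.14) and MT-ND5 (0.49) lay above 0 and did not pass. As a list the 13 messenger RNAs did not pass (camera adjusted p = 0.188). Without replicate 5, MT-RNR1 (0.76) did not pass and MT-ND5 (0.72) did; MT-ND3 (-0.68) passed as lower without replicate 4 (-0.67). MT-ND1 (-1.04) and MT-CYB (-0.77), the other 2 called lower, lost their calls without replicate 2 (-0.89 and -0.78) or 3 (-1.13 and -0.89), and MT-CYB also without replicate 4 (-0.60) or 5 (-0.83). With IL-2 on both platforms, MT-RNR2 was at 1.90 ± 0.21 and MT-RNR1 at 1.54 ± 0.33, and MT-ATP8 and MT-CO3 at -2.02 and -1.98. Genes of the mitochondrial genome took 3.51% of the reads on beads and 3.98% on GO-APP without IL-2. The ribosomal RNA genes were chosen after their values were seen.

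**Figure D3:**
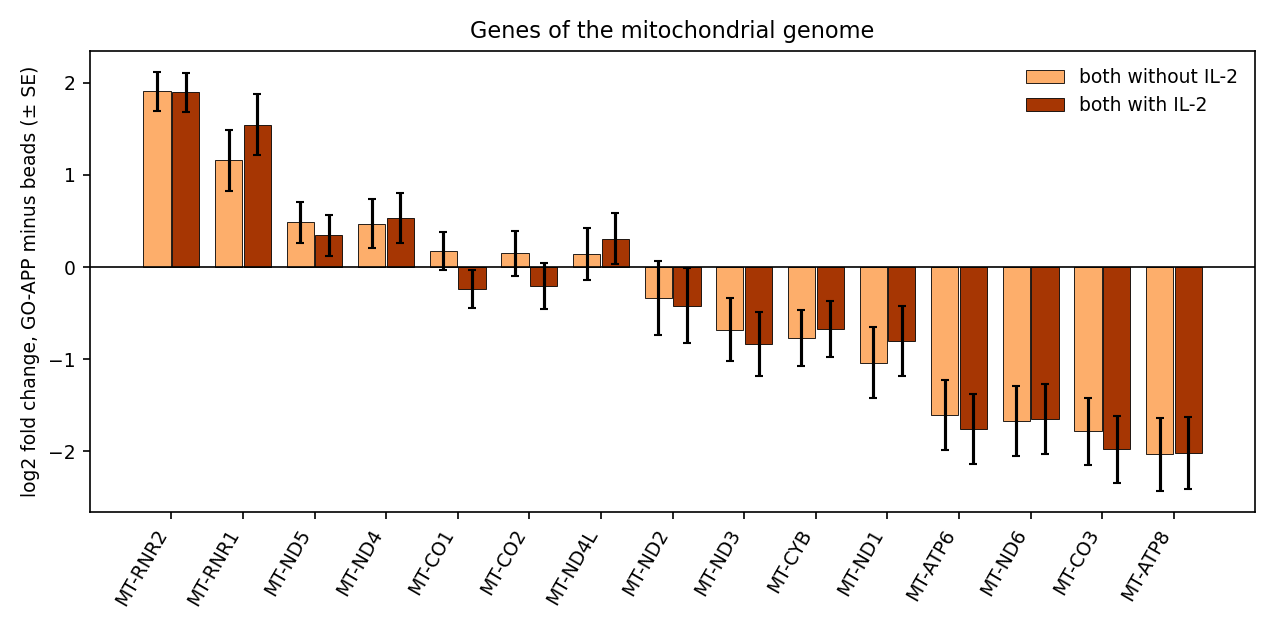
Log2 fold change of each mitochondrial gene, GO-APP minus beads, with bars for the pair of groups without IL-2 (light) and the pair with IL-2 (dark) and error bars for limma's SE (n = 4 libraries per group). MT-RNR2 stands highest, at 1.91 and 1.90, and MT-ATP8 lowest, at -2.04 and -2.02.

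Between the cultures that both received IL-2, 7974 genes differed by platform. ADM was at 1565 ± 909 on GO-APP against 1.78 ± 0.682 on beads (limma adjusted p = 5.79e-08). From log2(value + 1), which understates the fold at such low values, its rise was 511-fold (SE 0.58 on the log2 scale). LAG3 was at 16900 ± 1704 against 869.1 ± 294 (log2 4.34 ± 0.29, limma adjusted p = 6.6e-08) and CCR2 at 2.08 ± 1.97 against 948.1 ± 653 (-7.98 ± 0.98, 1.04e-05). The 7974 genes were 51.0% of those tested, 3913 up and 4061 down, 2712 and 3020 by at least 2-fold, and 7728 in 1 direction in all 4 donors. MT1G rose by 9.30, MT1H by 8.89, MT3 by 8.79, EEF1A2 by 7.98, the adhesion gene IGLON5 by 7.14, the homeobox gene BARX1 by 7.07, the growth factor binding protein IGFBP2 by 6.91 and HES4 by 6.89 on the log2 scale, and MT1M was at least 125-fold higher. MEOX1 was at -6.58, PTGDR2 at -6.23, VSIG1 at -6.13, RAP1GAP2 at -6.00, TMEM229B at -5.99 and GPA33 at -5.75. ZNF469 and B3GALT2 had no read on GO-APP with IL-2 and were at least 31.6-fold and 35.5-fold lower.

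Most group changes had the direction seen without IL-2. Hypoxia genes gave 29 up and 0 down of 32, median 2.84 (camera adjusted p = 9.53e-12; adjusted p = 0.307 with an estimated correlation), ATF4 response genes 30 and 1 of 34, median 2.02 (1.32e-09; adjusted p = 0.467 with an estimated correlation), and ribosomal proteins 43 and 0 of 48, median 0.83 (2.12e-07; adjusted p = 0.748 with an estimated correlation). Metallothioneins gave 9 and 0 of 11 (9.33e-06; adjusted p = 0.307 with an estimated correlation), glycolysis 16 and 0 of 22 (1.9e-05; adjusted p = 0.65 with an estimated correlation), immediate early genes 18 and 1 of 27 (0.000123; adjusted p = 0.451 with an estimated correlation) and mitosis 24 and 0 of 40, median 0.98 (0.000429; adjusted p = 0.748 with an estimated correlation). The unfolded protein response gave 16 and 0 of 23 (0.00151; adjusted p = 0.535 with an estimated correlation), NF-kB targets 14 and 2 of 23 (0.00213; adjusted p = 0.307 with an estimated correlation), and activation genes 12 and 1 of 23 (0.00364; adjusted p = 0.613 with an estimated correlation). Type I interferon genes gave 3 up and 23 down of 43, median -1.65 (0.00249; adjusted p = 0.748 with an estimated correlation).

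Of p53 targets, 17 rose and 5 fell of 28 (camera adjusted p = 0.00681; adjusted p = 0.307 with an estimated correlation), of IL-2 and STAT5 targets 17 and 2 of 29 (0.00681; adjusted p = 0.748 with an estimated correlation), and of nuclear RNAs that serve as a sign of RNA quality 5 and 0 of 7 (0.026; adjusted p = 0.467 with an estimated correlation). Cholesterol and fatty acid synthesis genes gave 13 up and 3 down of 28, median 0.62 (0.0313; adjusted p = 0.748 with an estimated correlation), heat shock genes 5 and 0 of 14 (0.0325; adjusted p = 0.748 with an estimated correlation) and oxidative phosphorylation 11 and 0 of 44 (0.0457; adjusted p = 0.823 with an estimated correlation). Adjusted over the list alone, the counts up and down were 29 and 0 (hypoxia), 30 and 2 (ATF4), 47 and 0 (ribosomal proteins), 9 and 0 (metallothioneins), 17 and 0 (glycolysis), 19 and 1 (immediate early), 24 and 0 (mitosis), 16 and 0 (unfolded protein response), 17 and 2 (NF-kB), 12 and 1 (activation), 3 and 23 (type I interferon), 17 and 5 (p53), 17 and 3 (STAT5), 5 and 0 (nuclear RNA), 13 and 3 (cholesterol), 5 and 0 (heat shock), and 4 and 0 (oxidative phosphorylation). Interferon gamma response (0.0739) and adhesion genes (0.0797) did not pass.

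With the donor block alone, naive and central memory genes (3 up, 13 down of 28; adjusted p = 0.129 and, blocked, 0.048), MHC class II genes (1 up, 5 down of 13; 0.129 and 0.048) and dendritic cell markers (4 up, 0 down of 7; 0.099 and 0.0414) passed as well; in that fit they had adjusted p = 0.566, 0.688 and 0.445 with an estimated correlation. CCR7 fell by 2.98, TCF7 by 1.92 and IL7R by 2.48 on the log2 scale (adjusted p = 0.000715, 0.0337 and 0.042). GZMB (4.25), IFNG (3.48), PDCD1 (2.02), IL2RA (1.84), CD4 (0.90) and IL2 (2.42; 28.6 ± 17.6 against 3.90 ± 1.76) rose, while PRF1 (0.42), IL2RB (0.45), CISH (-0.53), MKI67 (0.07) and CD8A (-0.42, adjusted p = 0.599 and, blocked, 0.0444) did not pass. Calls were lost for TCF7 without replicate 2 (-1.49) or 5 (-2.10), for IL7R without replicate 3 (-2.66), 4 or 5 (-2.22), for IL2 without replicate 4 (1.88) or 5 (2.13), and for CD4 without replicate 2 (0.74), 3 (0.87) or 5 (0.81). The blocked call of CD8A held without replicate 4 alone (-0.57). Dendritic cell markers summed to 3895 ± 2306 on GO-APP and 887.6 ± 395 on beads. Natural killer cell markers summed to 60260 ± 30850 and 17410 ± 7653, and monocyte and macrophage markers to 3427 ± 2859 and 1381 ± 368. The median marker was at 6.94 and 3.90, 114.7 and 84.35, and 9.29 and 6.15 in that order. Of the genes higher on GO-APP without IL-2, 2981 (89.8%) were also higher with IL-2, against 831 expected from independent lists. Of the genes lower, 3074 (91.2%) were shared, against 875, and 0 genes changed in opposite directions. Both comparisons come from the same donors and a shared fit, so the lists are not independent and their overlap is no replication.

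**Figure D4:**
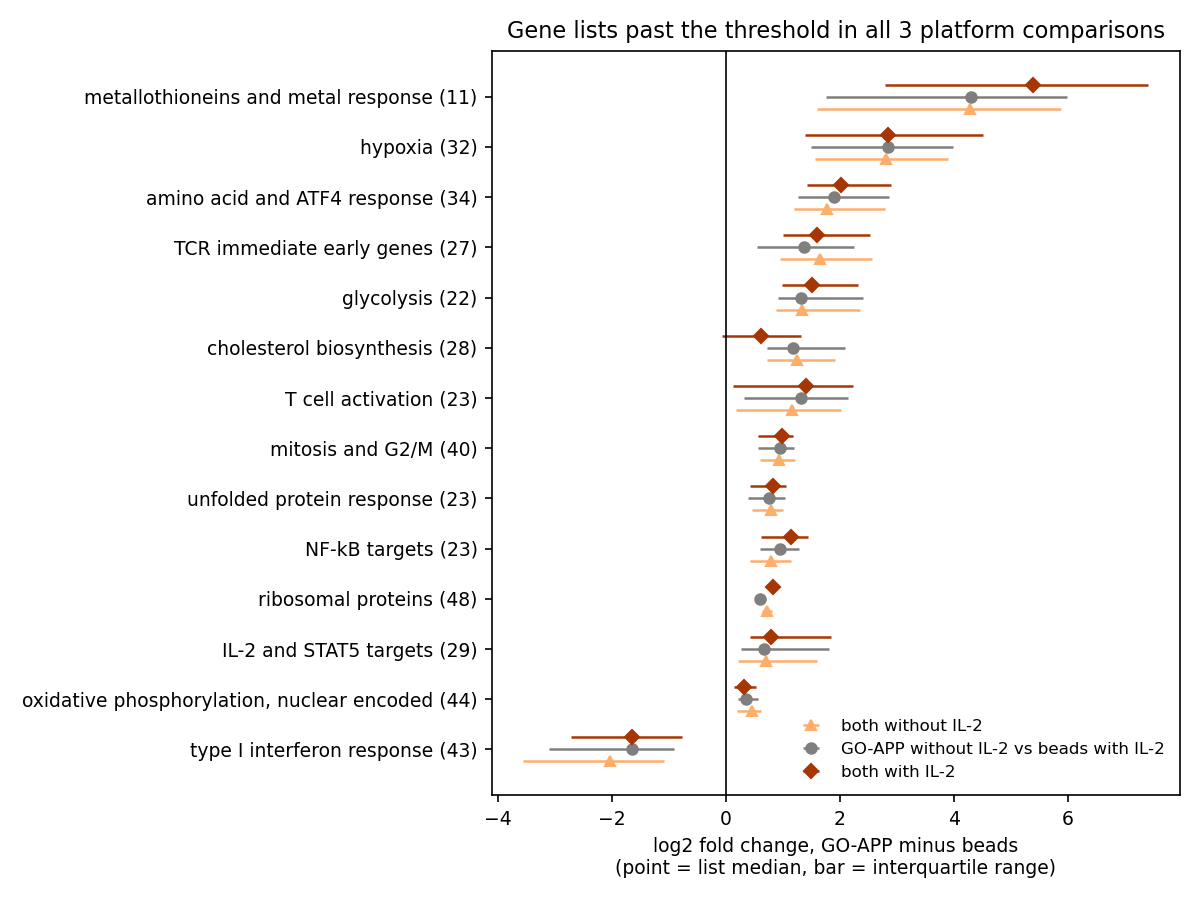
Median log2 fold change, GO-APP minus beads, of the members of each gene list that passed in all 3 platform comparisons, with the interquartile range as a bar, the number of tested members in brackets and 1 marker per comparison. Metallothioneins lie highest, at 4.29, 4.31 and 5.38, hypoxia genes at 2.81, 2.85 and 2.84, and type I interferon response genes lowest, at -2.04, -1.64 and -1.65.

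Whether added IL-2 changed cells on beads was tested in the same donors. No gene passed: limma called 0 genes, with 50 genes at an unadjusted p under 0.05 (107 with the donor block, and 338 in the fit of only these groups with it), DESeq2 called 0 and edgeR 0, and 0 passed with the donor block. By chance alone, 782.1 genes would have an unadjusted p under 0.05, so the test is conservative here. The immediate early gene FOS had the smallest p among the named genes, at 86.8 ± 46.8 with IL-2 against 10.9 ± 8.02 without (log2 2.85 ± 0.76, limma adjusted p = 1, higher in 4 of 4 donors), and passed in the blocked fit without replicate 4 (3.07, adjusted p = 0.0314). Other genes with small p, none passing, were KRT1 (1.95), NFATC4 (0.95), C1orf21 (0.88) and MXRA7 (0.51) with positive values, and MATR3 (-0.90), UBE2W (-0.59), BMI1 (-0.52), ZNF267 (-0.44) and CERS6 (-0.42) with negative ones. Of the key genes, LAG3 was at -0.16 ± 0.29, GZMB at 0.24 ± 0.91, IFNG at 0.01 ± 0.49, IL2RA at -0.02 ± 0.47, IL2RB at 0.15 ± 0.33, CISH at 0.20 ± 0.58 and IL2 at -0.57 ± 0.73. PRF1 (0.28), CD4 (0.07), CD8A (0.21), CCR7 (-0.32), TCF7 (-0.11), IL7R (0.35), PDCD1 (0.07) and MKI67 (-0.05) did not pass either.

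Small shifts of whole lists were seen with IL-2 on beads, with 0 members passing over all genes tested. Cytotoxic effector genes were shifted upwards by a median log2 fold change of 0.25 (camera adjusted p = 8.28e-06; adjusted p = 0.263 with an estimated correlation). FGFBP2 was at 0.99, ZNF683 at 1.83 and granulysin (GNLY) at 1.12. Type I interferon genes were shifted downwards by a median of -0.38 (6.49e-05; adjusted p = 0.996 with an estimated correlation). IFIH1 was at -0.47 and OAS3 at -0.64, each lower in all 4 donors. Upward shifts also passed for ribosomal proteins (median 0.11, 0.00128; adjusted p = 0.996 with an estimated correlation), gamma delta T cell genes (0.42, 0.00366; adjusted p = 0.467 with an estimated correlation) and B and plasma cell markers (0.38, 0.0302; adjusted p = 0.996 with an estimated correlation). Downward shifts passed for p53 targets (-0.07, 0.00874; adjusted p = 0.263 with an estimated correlation), NF-kB targets (-0.14, 0.0113; adjusted p = 0.332 with an estimated correlation) and nuclear RNAs (-0.12, 0.0017; adjusted p = 0.263 with an estimated correlation).

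The nuclear RNA MALAT1 was at 4814 ± 2182 with IL-2 on beads and 21730 ± 22990 without, a measured difference in a sign of RNA quality beside these shifts. Adjusted over the list alone, 1 nuclear RNA fell and 0 rose, and 0 members of the other 7 lists passed. Natural killer cell markers (median 0.16, adjusted p = 0.0944 and, blocked, 0.0213) and CD8 lineage genes (0.14, 0.14 and 0.00629) passed with the donor block, with adjusted p = 0.759 and 0.441 with an estimated correlation in that fit. B and plasma cell markers summed to 3329 ± 1404 with IL-2 and 3032 ± 1792 without.

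On GO-APP, added IL-2 went with lower cholesterol and fatty acid synthesis genes as a group. Their median log2 fold change was -0.56 over 28 genes, with 0 passing over all genes tested and 11 falling adjusted over the list alone (camera adjusted p = 5.7e-15; adjusted p = 0.448 with an estimated correlation). The desaturase FADS2 was at 1092 ± 1538 with IL-2 against 3205 ± 864 without (-2.45 ± 0.60, limma adjusted p = 0.347; -3.14 and adjusted p = 0.00125 without replicate 4), IDI1 at -0.79 ± 0.20, FDFT1 at -0.74 ± 0.21 and DHCR7 at -0.95 ± 0.28, each lower in 4 of 4 donors. CREB3L3, a transcription factor of lipid metabolism (chromosome 19, 4153601 to 4173054), was at 363.6 ± 299 with IL-2 against 18.2 ± 10.8 without (3.90 ± 0.65; adjusted p = 0.121 and, with the donor block, 0.000209). The cholesterol exporter ABCA1 (chromosome 9, 104781002 to 104928237) was at 563.3 ± 452 against 34.5 ± 38.8 (4.36 ± 0.82; adjusted p = 0.141 and, blocked, 0.00217). In the blocked fits that left out 1 replicate, CREB3L3 passed in all 4, and ABCA1 passed without replicate 4 (5.19) but not without replicate 2, 3 or 5.

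How many single genes were called for IL-2 on GO-APP depended on the fit. Limma called 0, with 1044 at an unadjusted p under 0.05 (782.1 expected by chance), edgeR 0, DESeq2 25 (23 up, 2 down), and limma with the donor block 2, CREB3L3 and ABCA1. A pseudocount of 10 gave 21, and the fit of only the groups compared with the donor block 45 (42 up). Without replicate 4, limma called 4 genes (CREB3L3, FADS2, PCYT2 and GPR132), and 10 with the block. The myeloid receptor TREM1 was at 59.2 ± 24.7 against 6.59 ± 3.70 (3.02 ± 0.48, adjusted p = 0.121), the heat shock factor HSF4 at 2568 ± 298 against 537.5 ± 195 (2.34 ± 0.42, 0.123) and JPH2 at 2.79 ± 0.49 (0.123). DESeq2 called all 3, as did a pseudocount of 10 and the fit of only the groups compared with the donor block, and HSF4 also passed in the blocked fit without replicate 4 (2.05). On the lower side PCYT2 (-1.55 ± 0.33), GPR132 (-1.01 ± 0.23), TMEM250 (-0.86 ± 0.20) and TRAPPC13 (-0.65 ± 0.16) had the smallest p after the synthesis genes and did not pass. Among key genes, LAG3 was at 0.71 ± 0.29, IFNG at 0.68 ± 0.49, IL2 at 1.04 ± 0.73, GZMB at 0.43 ± 0.91, CCR7 at -1.85 ± 0.61 and CISH at -0.89 ± 0.58; of these, CCR7 passed in the blocked fit without replicate 4 (-2.37, adjusted p = 0.00499). IL2RA (-0.15), IL2RB (0.20), PRF1 (0.01), CD4 (-0.05), CD8A (0.00), TCF7 (-0.60), IL7R (-0.81), PDCD1 (0.28) and MKI67 (-0.37) did not pass either.

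**Figure D5:**
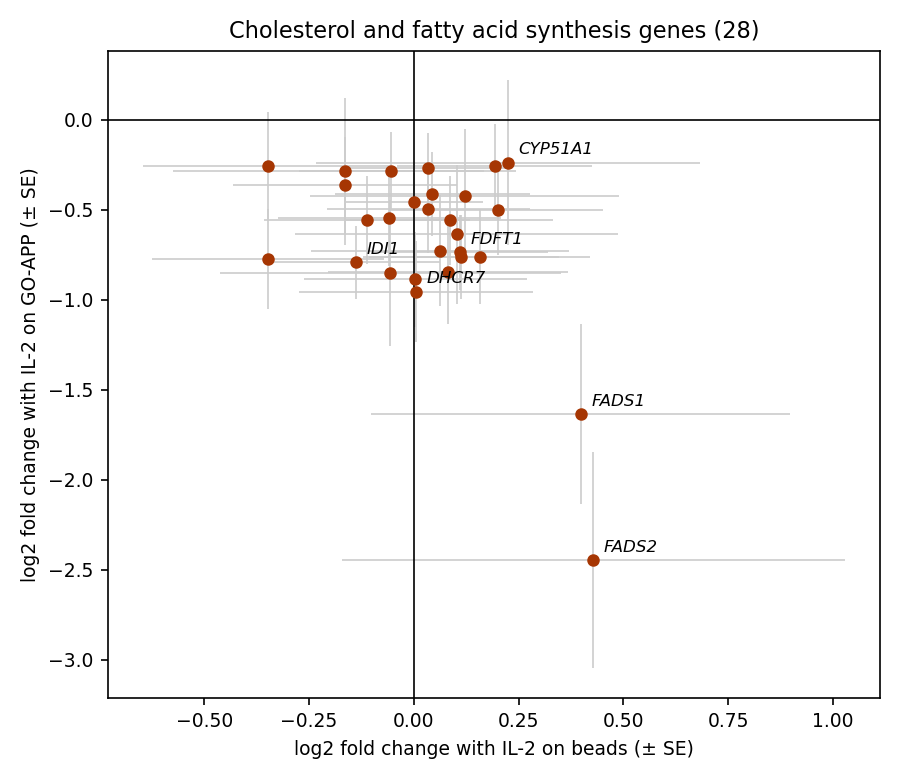
Log2 fold change with IL-2 of 28 cholesterol and fatty acid synthesis genes on beads (x axis) and on GO-APP (y axis), each point a gene with limma's SE as bars (n = 4 libraries per group). Most points lie below 0 on the y axis, with a median of -0.56 and FADS2 at -2.45.

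Other lists were shifted upwards with IL-2 on GO-APP, with 0 members passing over all genes. Metallothioneins had a median of 1.13 (camera adjusted p = 0.000114; adjusted p = 0.763 with an estimated correlation). MT1F was at 1.63 ± 0.68 and MT1X at 1.39 ± 0.58, each higher in 3 of 4 donors. Cytotoxic effector genes had a median of 0.35 (2 rose and 0 fell adjusted over the list alone) (0.00346; adjusted p = 0.763 with an estimated correlation). GZMA was at 1819 ± 462 against 598.3 ± 278 (1.69 ± 0.43) and FGFBP2 at 1.39 ± 0.41. Ribosomal proteins had a median of 0.22 (7.74e-05; adjusted p = 0.993 with an estimated correlation). RPL28 was at 0.55. Histone genes had a median of 0.44 (1 rose adjusted over the list alone) (0.00346; adjusted p = 0.897 with an estimated correlation). HIST1H1C was at 1.69 ± 0.39. Monocyte and macrophage markers had a median of 0.85 (1 rose adjusted over the list alone) (0.00123; adjusted p = 0.897 with an estimated correlation). SPP1 was at 2.34 ± 0.67, LGMN at 1.25 and LYZ at 1.85. Their sum was 3427 ± 2859 with IL-2 and 1431 ± 638 without, a measured difference beside all the groups named for this comparison. Natural killer cell markers passed with the donor block (median 0.39; adjusted p = 0.143 and, blocked, 0.0346; adjusted p = 0.787 with an estimated correlation in that fit).

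The interaction tests whether the IL-2 difference itself differed between the platforms. The dose on GO-APP is not given, so a difference in dose is not separated from the platform here or in the comparison with IL-2 on both. The cholesterol and fatty acid synthesis list differed, with a median log2 difference of -0.59 and FADS2 at -2.88 ± 0.85, FADS1 at -2.03 ± 0.71 and MVK at -0.88 ± 0.33 (camera adjusted p = 3.71e-13; adjusted p = 0.212 with an estimated correlation). On beads, CREB3L3 was at 397.9 ± 193 with IL-2 and 393.5 ± 146 without; its interaction was called with the donor block (adjusted p = 0.0166), a call that held without replicate 4 (4.40) and was lost without replicate 2, 3 or 5. Limma called 0 genes for the interaction without the block, with 381 at an unadjusted p under 0.05, DESeq2 1, edgeR 0 and the blocked fit 1 gene, CREB3L3. Without replicate 4, limma called 2 (CREB3L3 and FADS2), and 3 with the block, ABCA1 being the third. For the interaction, CREB3L3 and ABCA1 were chosen after their values were seen. Positive differences passed for metallothioneins (median 0.97, 0.000122; adjusted p = 0.431 with an estimated correlation), nuclear RNAs (0.39, 0.000493, 3 rose adjusted over the list alone; adjusted p = 0.212 with an estimated correlation), histones (0.61, 0.000493; adjusted p = 0.827 with an estimated correlation), p53 targets (0.35, 0.00164; adjusted p = 0.212 with an estimated correlation) and type I interferon genes (0.39, 0.00598; adjusted p = 0.999 with an estimated correlation). Monocyte and macrophage markers passed with the block (0.41; adjusted p = 0.0569 and, blocked, 0.0288; adjusted p = 0.975 with an estimated correlation in that fit). The key genes did not pass; LAG3 was at 0.87 ± 0.41, IL2 at 1.61 ± 1.03 and CCR7 at -1.52 ± 0.86.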

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

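Of the tests in this part, those of library scaling, of monocyte RNA, of more mitochondrial RNA of every kind, of lower cell division and of sterol load were chosen after the result was seen.

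Regrouping the 8 libraries of each platform comparison in all 35 ways gave 6761 genes for the real grouping of GO-APP without IL-2 against beads with IL-2, 6692 for both without IL-2 and 7974 for both with IL-2. In each, 1 of 35 groupings (the real one) gave as many genes, and the highest other gave 0. That share is the smallest that 35 groupings allow, so it argues against chance without excluding it. The 8 groupings that part both libraries of every donor also gave 0 at most, the real one aside. Among these alone, the smallest possible share is 1 of 8. For the 3 IL-2 comparisons the real count was 0, so all groupings gave as many by construction (35 of 35 on beads, 35 of 35 on GO-APP, and 100 of 100 random assignments for the interaction), and this says nothing about chance. The highest other counts were 1513, 484 and 7265. Groupings within a platform that call many genes point to a structure of the samples, such as the donors. The random assignments for the interaction also mixed the platforms, so the 7265 may reflect the platform as well as the donors. On each platform, groupings that part every donor's pair of libraries gave 0 at most; none of that kind was run for the interaction.

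The first pattern is the higher level of hypoxia genes on GO-APP, both without IL-2. Library scaling moves all genes of a library alike, so by itself it cannot set a list apart from other genes. In each donor's pair the median of the list lay above that of the other genes, by 2.742 ± 0.800 on average (SD over 4 donors). The list was followed up because camera had set it apart from other genes. This value therefore repeats that result and is no separate test of scaling. TMM moved the median of all genes by -0.016 and so tested nothing. A trend on GC content and transcript length is argued against by the median of 2.92 after its removal (lower quartile 1.53). Monocyte or macrophage RNA is argued against by markers that summed to 0.785% of the rise of the list, or 1.48% at mean plus 2 SD; 16 of these markers were tested, with a median log2 fold change of 0.77. LYZ was at 43.6 on GO-APP against 256.5 on beads, CD14 at 6.49 against 4.29 and CSF1R at 48.9 against 8.06, and the labels name no sort. The platform, which the design names, stays open as a biological source, as a hypothesis only, and oxygen in the cultures was not measured in these data.

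The second pattern is mitochondrial ribosomal RNA, higher on GO-APP while most mitochondrial messenger RNA was not. The messengers' median log2 fold change was -0.68 (upper quartile 0.15), so mitochondrial RNA was not higher for every kind. The pattern was defined by these same messengers, so this value restates it and is no separate test. Carry-over of ribosomal RNA from library preparation cannot be told apart: the 2 nuclear ribosomal RNA features in the file had a log2 fold change of 0.249 ± 0.763, with group means from 0 to 4.98 counts, too few to decide. A platform effect on the mitochondria was not tested.

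The third pattern is the lower level of cholesterol and fatty acid synthesis genes with IL-2 on GO-APP. A single donor is argued against, since the largest camera adjusted p without any donor was 6.79e-11 (range from 5.05e-17). The median of the list minus that of the other genes in each donor's pair was -0.628 ± 0.299 (SD over 4 donors). A factor shared by all genes cannot make such a distance. Camera had already picked the list by it, so this is no separate test of scaling. Lower cell division is argued against by a median of 0.051 for mitosis genes (interquartile range -0.17 to 0.16). Higher sterol load stays open: 14 liver X receptor targets other than ABCA1 did not pass limma's camera and had a median log2 fold change of 0.011 (interquartile range -0.20 to 0.17). Of these, 8 were positive, and members that go both ways decide nothing. Among such targets, ABCG1 (1.15 ± 0.61) and MYLIP (1.42 ± 0.54) were higher with IL-2 in 4 of 4 donors. Both were chosen after their values were seen. Neither passed (limma adjusted p = 0.804 and 0.657, and 0.384 and 0.263 with the donor block). All of these p values use the preset correlation; with an estimated one the list itself had adjusted p = 0.448.

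Lists whose IL-2 difference depended on platform in the interaction test were cholesterol and fatty acid synthesis (adjusted p = 3.71e-13), metallothioneins (0.000122), histones (0.000493), nuclear RNAs (0.000493), p53 targets (0.00164) and type I interferon genes (0.00598). These 6 calls were lost when the correlation was estimated: in that order they had adjusted p = 0.212, 0.431, 0.827, 0.212, 0.212 and 0.999 with an estimated correlation. For the gene CREB3L3, the difference passed with the donor block (0.0166).

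In 41 of 804 groups of 4 libraries, the most distant library's gap to its nearest neighbour, divided by the group's range, passed Dixon's value of 0.829; chance gives about 1 in 20, or 40. By group there were 11, 11, 7 and 12 (beads without, beads with, GO-APP without, GO-APP with IL-2). For beads without IL-2, the gap shares were 0.84 for ABCA1, 0.949 for CREB3L3, 0.937 for LAG3, 0.849 for PCYT2, 0.932 for VEGFA, 0.837 for CTSS, 0.898 for GNLY, 0.956 for RPL3, 0.867 for SNHG5, 0.958 for STARD4 and 0.862 for TNFRSF10B. On beads with IL-2 they were 0.857 for the share of reads in the 10 most abundant genes, 0.865 for KRT1, 0.856 for BATF3, 0.859 for FCER1G, 0.893 for GAS5, 0.857 for GZMA, 0.85 for GZMM, 0.931 for HSP90B1, 0.862 for LYZ, 0.894 for MYO1F and 0.836 for P4HA1. With GO-APP and no IL-2 they were 0.897 for CCL22, 0.953 for COX8A, 0.866 for NDUFB8, 0.917 for RPS13, 0.883 for RPS25, 0.891 for RPS6 and 0.852 for UQCRH. With GO-APP and IL-2 they were 0.905 for GPR132, 0.87 for LAG3, 0.831 for ZNF267, 0.829 for BCL6, 0.873 for FCER2, 0.838 for IER3, 0.924 for KIF2C, 0.851 for PIM1, 0.86 for RPL28, 0.878 for RPS18, 0.841 for RPS6 and 0.852 for SAMD9L.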

How the results depend on the processing

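Of the alternatives here, only the fit of the groups compared with the donor block was chosen after the data were seen. The counts of the 3 platform comparisons stayed within 1.5 times under all alternatives run (5039 to 7903, 4737 to 7827 and 6049 to 8984 genes with each replicate left out included), with 0 genes called in the opposite direction; the replicate block gave 7903, 7827 and 8984, and DESeq2 7298, 7236 and 8344. For IL-2 on beads, the count was 0 except with replicate 4 left out and the block, which gave 1 (FOS, adjusted p = 0.0314); the range over replicates left out was 0 to 1, and the replicate block gave 0. For IL-2 on GO-APP, the count of 0 became 21 with a pseudocount of 10, 2 with the replicate block, 25 with DESeq2, and 45 with only the groups compared and the block. With replicates left out it ranged from 0 to 10, the highest being without replicate 4 with the block, and 4 without replicate 4 and no block (CREB3L3, FADS2, PCYT2 and GPR132). The interaction's 0 became 1 with the replicate block and 1 with DESeq2, and ranged from 0 to 3 with replicates left out (2 without replicate 4, 3 with the block as well). The causes were not tested.

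Lists past the threshold numbered 17, 16, 17, 8, 6 and 6 of 42 in the order of the 6 comparisons. With an estimated correlation it was 0 in all 6; with fry, which only asks whether genes move one way, 17, 22 and 24 in the platform comparisons, with 13 of 17, 14 of 16 and 14 of 17 calls kept, and 0 in the 3 IL-2 comparisons; the cause was not tested. Under TMM scaling all 252 list results kept their call, and with a pseudocount of 10, 1 was lost and 2 gained. The replicate block ended 1 list call and added 13, each given with its result, and it changed no other call of a list.

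Variance shares moved beyond their jackknife SE without the filter: platform 46.1%, IL-2 3.19%, interaction 2.99% and residual 26.5%; a pseudocount of 0.1 gave a residual of 19.6%. With each replicate left out, ranges were 57.7% to 63.9% for platform, 17.2% to 20.1% for donor, 2.06% to 3.37% for IL-2, 1.77% to 2.87% for the interaction and 14.2% to 16.8% for the residual. The causes were not tested.

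Of 134 calls of single genes in the platform comparisons (a gene counts once per comparison, mitochondrial genes and genes chosen later included), DESeq2 and the replicate block kept all 134, edgeR lost 5, no filter 8, a pseudocount of 0.1 lost 2, and leaving out replicates lost 51 of 536; 0 reversed. Of 200 results not called, DESeq2 called 15, the block 14, a pseudocount of 10 called 6, edgeR 3 and TMM 1; only the groups compared with the block called 23 of 172, and blocked fits that left out 1 replicate 57 of 800. At 16671041 reads or more, depth limits genes under about 3 counts per library.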

Other observations

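Of the values here, the test of the platform axis and the comparisons of gene types were chosen after the data were seen.

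Long noncoding and zinc finger genes were lower on GO-APP more often than other genes. Without IL-2, 36.6% of 1785 long noncoding genes fell (654) against 19.8% of 12627 protein coding genes, with a median log2 fold change of -0.69 (two-sided Fisher's exact p = 9.45e-53). Genes whose symbols mark zinc finger proteins, which regulate transcription, fell in 44.6% of 487 cases (217) against 18.8% of other protein coding genes (Fisher's exact p = 9.4e-37). With IL-2 on both platforms, 43.2% of long noncoding and 54.0% of zinc finger genes fell, against 23.98% and 22.8%. Small nucleolar and small Cajal body RNAs, counted together, rose in 15 of 40 cases (37.5%) without IL-2, against 23.3% of protein coding genes (Fisher's exact p = 0.0395). With IL-2 on both platforms they rose in 30 of 40 (75%), against 26.9% of protein coding genes (Fisher's exact p = 3.51e-10, median 2.14). Genes are not independent replicates, and the strand setting of the counting is not given, so reads of a noncoding gene and an overlapping gene cannot be told apart.

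Whether IL-2 on GO-APP extends the platform difference is not settled by a projection on the platform axis. That axis used libraries with and without IL-2, so it holds part of the other donors' IL-2 difference on GO-APP. Any IL-2 difference shared by donors therefore raises the value, whatever its relation to platform. The cholesterol and fatty acid synthesis list and CREB3L3 moved with IL-2 towards their bead levels. Each donor's IL-2 difference on GO-APP, projected on the platform axis of the other donors, was above 0 in 4 of 4 donors, at 12.1% ± 4.51 (SD) of the platform distance; on beads it was -0.715% ± 4.38, above 0 in 2 of 4, and the exact two-sided sign-flip p of 0.125 on GO-APP is the smallest that 4 donors allow.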
